A study of Homo sapiens with 13 samples.

How the data were processed

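DNA methylation was measured at CCCGGG sites by digital restriction enzyme analysis, in which genomic DNA is cut first with SmaI, which is blocked by CpG methylation, and then with XmaI, which is not. The end left by each enzyme marks a sequenced molecule as unmethylated or methylated. The 13 libraries came from 2 cord blood samples, 4 adult blood donors, 1 acute myeloid leukaemia (AML) bone marrow and the leukaemia cell lines HEL and K562. The adult donors had 2, 2, 1 and 3 technical libraries. Groups, donors and technical libraries were taken from the sample labels.

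Per the file headers, the authors deposited for each library the counts of methylated and unmethylated reads at 374170 listed sites, with site identifiers and positions on build hg18, the build named in the submitters' processing notes. The aligner and read filters are not given in the sources used here. The deposited percent methylation per site was not the plain share of methylated reads. It was compared with the deposited counts, and in each library it followed from the odds of methylated to unmethylated reads multiplied by a single factor, between 0.858 and 2.76 over the 13 libraries. With that factor the deposited percentages were recovered within 0.1 points at 100% of covered sites in 11 libraries, at 89.1% in the library of adult donor 3 and at 92.1% in the first library of adult donor 4. Per the labels' protocols, DNA standards of 5 known methylation levels were added to the samples before digestion, but how the factors were set is not given in the sources used here.

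The planned tests assumed plain counts. Because the deposited percentages carry the correction, the methylated reads entering the tests were the deposited percent times the reads at a site, summed over the technical libraries of a donor, and the uncorrected counts were run as an alternative chosen after seeing the data. A correction factor above 1 raises intermediate levels most and leaves 0% and 100% in place, so a factor that is wrong for a library shifts its sites in a single direction. Sites on X and Y were left out, as were sites with under 20 reads in any sample compared. PCR reads carry no molecular identifiers here, so intervals and limits cover counting error only.

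Cord blood and the 3 leukaemia samples were each compared with the 4 adult donors by a quasi-binomial logistic model per site. The Pearson dispersion was moderated across sites with limma 3.58.1 (squeezeVar, with a trend on log total reads) and floored at 1, and p-values were adjusted by the Benjamini-Hochberg method. A site was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. The tests were two-sided and run in R 4.3.3. Each leukaemia library was also compared alone. A site was then called gained or lost when it differed by at least 30 points from the adult mean, lay outside the range of the 4 donors and had an adjusted p under 0.05 in Fisher's exact test on the reads. That test compares libraries, not conditions. The same rule, applied to each adult donor against the other 3 and to each cord sample, gave the background. Mean methylation was compared by exact two-sided permutation tests. Intervals for single libraries are exact 95% Clopper-Pearson intervals of the read share, carried through the correction factor.

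Sites were classed by the adult mean as low (under 20%), intermediate (20 to 80%) or high (over 80%), and by the number of other listed sites within 500 bp. Named sites were chosen by a rule fixed before the data were examined. For each leukaemia library these were the 5 gained and 5 lost sites with the greatest difference and at least 100 reads in the library and in the adult sum. For cord blood these were the 5 higher and 5 lower sites with the greatest difference, and for the leukaemia group the 10 gained and 10 lost sites with the greatest change in the library that changed least, at most 1 site per 100 kb. The 5 windows of 100 kb with the most gained and the most lost sites were also taken, and only part of each set is printed. No hg18 gene annotation was used here, so the planned gene lists were not run and sites are given by position.

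The tests were checked on simulated reads with the real depths and adult levels, with 200 sites changed per comparison. A single spread, pooled over all sites of the adult donors, was given to every sample, leukaemia samples included. The real leukaemia samples were spread more widely, so the figures for leukaemia do not cover their real spread. For cord blood against adult blood, over 38196 sites, 33% of changes of 20 points and 81% of changes of 40 points were recovered, with 2 false calls. For leukaemia against adult blood, over 33619 sites, 55% and 71% were recovered, with 1 false call. The rule for a single library recovered 88% of changes of 40 points in AML, 85% in HEL and 88% in K562, with 2, 11 and 12 false calls. By that rule real adult donors against each other gained between 6 and 35 sites and lost between 11 and 62. The simulated false calls may thus be too few. In the simulation 11.3% of unchanged sites had an unadjusted p under 0.05 in the cord comparison and 6.97% in the leukaemia comparison. Alternatives were other read minimums and difference thresholds, the first technical library only, limma on log2 odds, unfloored dispersion, cord blood among the controls, thinned reads, each sample left out and the replicate number as a block.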

Results

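Methylation at CCCGGG sites was compared between healthy cord blood (2 samples), healthy adult white blood cells (4 donors, 8 libraries), the bone marrow of 1 AML patient, and the cell lines HEL, an erythroleukaemia line, and K562, a line from chronic myelogenous leukaemia in blast crisis. The series asks how similar healthy blood cells are to each other and how leukaemia differs from them. Library totals were 120476642 and 113023565 reads for cord blood, 9178473 for AML, 7169746 for HEL and 10075503 for K562. The 8 adult libraries held between 12404854 and 59705192 reads. At least 20 reads were present at 38693 autosomal sites in AML, 52218 in HEL and 48582 in K562. Of the 33436 sites covered in all 9 samples, 20556 were low in adult blood, 2745 intermediate and 10135 high. Sites with 3 or more neighbours within 500 bp were low in 84.2% of cases, against 50.1% of sites with 1 to 2 neighbours. AML, HEL and K562 had no replicates.

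Adult blood libraries were close to each other at most sites. Over the 34990 sites covered in all 8 libraries, the median absolute difference between 2 libraries averaged 0.64 points within a donor (5 pairs) and 0.778 points between donors (23 pairs). The difference passed an exact two-sided permutation test over 1680 assignments of libraries to donors (p = 0.0345), but not with 1 library left out in 4 of 8 cases (exact permutation p = 0.1 without the second library of donor 1, 0.21 without either library of donor 2 and 0.0571 without donor 3). At sites intermediate in adult blood the corresponding values were 6.04 and 8.85 points (exact permutation p = 0.00595). Pairs from 1 donor had between 12 and 45 sites that differed by over 30 points, and pairs from different donors between 53 and 336. On uncorrected counts neither difference was detected: the within-donor and between-donor means were 0.663 and 0.686 points over all sites (exact permutation p = 0.71) and 8.79 and 8.90 points at intermediate sites (exact permutation p = 0.908). No 2 libraries held identical counts, and technical libraries of a donor differed in read totals per site by more than sampling noise.

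Cord blood was close to adult blood at most sites, with a median absolute difference from the adult mean of 0.612 and 0.6 points in the 2 samples. Of 38196 sites, 1257 (3.29%) were called, 922 higher and 335 lower in cord blood. Sites without a call need not be alike, since the simulation recovered 33% of changes of 20 points. In the quasi-binomial model 8797 sites had an unadjusted p under 0.05, where 11.3% of unchanged sites did in the simulation. Most calls lay at intermediate sites, where 19.5% of 3122 sites were higher and 7.08% lower, against 0.949% higher and 0.0902% lower among 23293 low sites. Among 11781 high sites the directions were nearly even, with 0.772% higher and 0.789% lower. Adult blood averaged 94.6% at high sites and 1.47% at low sites. Room to rise by 10 points at high sites, or to fall by 10 points at low sites, was therefore limited, which bounds the balance in these classes. The site with the greatest gain, at position 100301622 of chromosome 7, was methylated at 99.6% in cord blood (n = 2) and 10.4% ± 5.13 in adult blood (SD, n = 4; 3624 adult reads). Position 71440469 of chromosome 16 was at 74.4% in cord blood and 4.13% ± 2.13 in adult blood, and position 75315878 of chromosome 4 was at 75.8% and 7.85% ± 2.78. On chromosome 22, position 44828478 was at 65.6% in cord blood and 2.18% ± 1.40 in adult blood, while position 44835840, within the next 10 kb, was at 0.4% and 58.0% ± 20.7. The lower sites were led by position 130195184 of chromosome 9, at 17.5% in cord blood and 90.9% ± 1.69 in adult blood, and position 10650546 of chromosome 1, at 19.1% and 84.4% ± 6.05. The 10 named sites were also called on uncorrected counts.

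The balance of directions in cord blood changed with the correction factor. On uncorrected counts 539 sites were higher and 698 lower, so the share higher moved from 73.3% to 43.6%. With log odds centred on intermediate sites it was 53.8%, but centring removes the median shift at the sites that hold most calls and so draws the share towards balance by construction. Of the calls, 484 higher and 316 lower were kept under both scalings. limma on log2 odds called 2 sites after adjustment, with 6673 at an unadjusted p under 0.05. Mean methylation was 35.4% ± 0.0977 in cord blood (SD, n = 2) and 34.5% ± 0.871 in adult blood (SD, n = 4), a difference of 0.902 points that did not pass the exact two-sided permutation test (p = 0.2, with 0.0667 the smallest p possible). The difference was 0.493 points without adult donor 1 and -0.244 points on uncorrected counts. With medians over sites it was -0.434 points (exact permutation p = 0.133), and with the replicate number as a block it was 1.40 points.

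**Figure D1:**
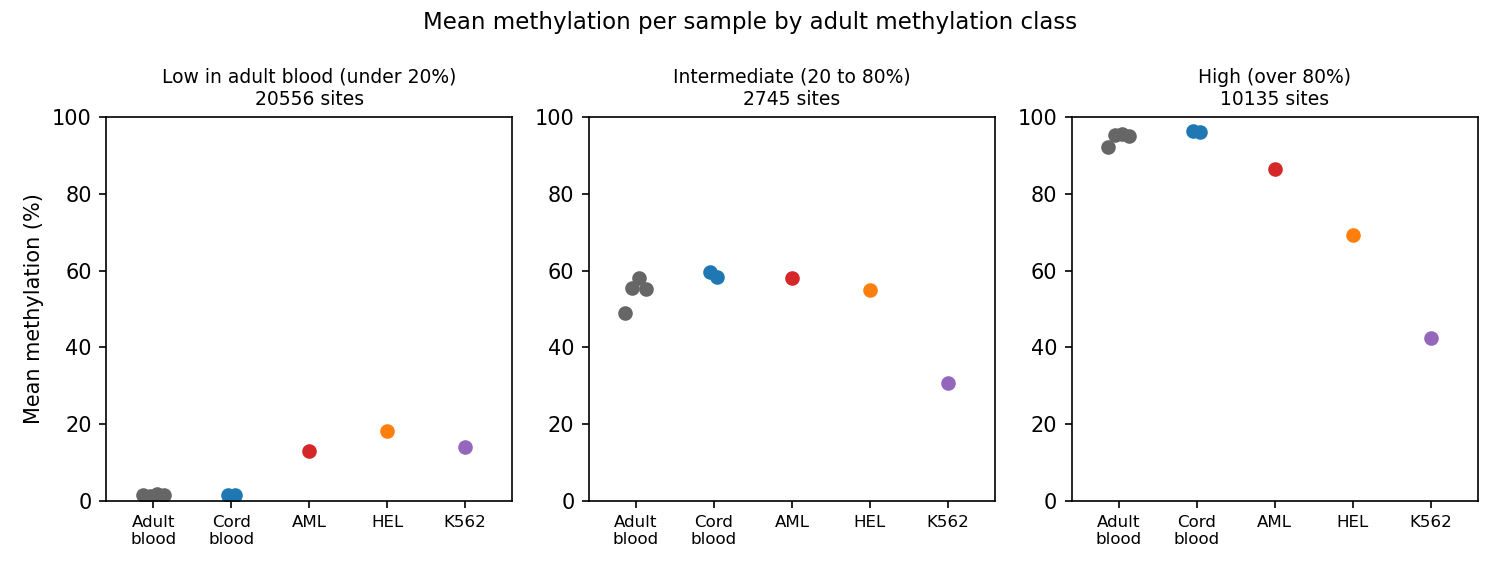
Mean methylation in percent of each sample (points) over autosomal sites classed as low, intermediate or high by the mean of the 4 adult donors, for adult blood, cord blood, AML, HEL and K562. At low sites the leukaemia samples lie at 12.9%, 18.2% and 14.1% against 1.47% in adult blood, and at high sites they lie at 86.5%, 69.4% and 42.5% against 94.6%.

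Leukaemia samples had a higher mean methylation at sites low in adult blood and a lower mean at sites high in adult blood. AML was bone marrow, HEL and K562 were cell lines, and the controls were adult blood. Leukaemia thus cannot be separated from tissue, cell type or culture, and the 3 samples are unlike single sources. Mean methylation of 20703 low sites was 15.0% ± 2.79 in leukaemia (SD, n = 3) and 1.46% ± 0.232 in adult blood (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest possible). Among the 10168 high sites the means were 66.1% ± 22.2 and 94.6% ± 1.60 (exact permutation p = 0.0286). High sites averaged 86.5% in AML, 69.4% in HEL and 42.5% in K562. With medians over sites in place of means, neither class passed the test (0.751 points at low sites, exact permutation p = 0.257; -25.2 points at high sites, exact permutation p = 0.0571). The median low site was at 0% in AML, 2.3% in HEL and 1.4% in K562, where adult donors lay between 0.138% and 0.8%, so the higher means came from part of the low sites. Over all sites the leukaemia mean was 33.2% ± 8.00 and the adult mean 33.9% ± 0.870 (exact permutation p = 0.914), whereas the median over all sites was 8.00 points higher in leukaemia (exact permutation p = 0.0286) and the mean without K562 was 3.98 points higher. In the other direction, the difference of means went from -0.787 to -5.31 points on uncorrected counts (exact permutation p = 0.0571), -3.74 at 100 reads (exact permutation p = 0.514), -4.05 without AML, -2.57 without HEL and -1.23 without adult donor 1. Classes set on adult donors 1 and 2 alone gave 1.72% at low sites and 95.5% at high sites in donors 3 and 4. Selecting sites on adult values thus moved other adult donors little. Low sites have little room to fall and high sites little room to rise. In samples unlike adult blood, the choice of classes therefore largely sets the direction of both differences.

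Of 33619 sites tested, 10706 (31.8%) were called, 5121 gained and 5585 lost. Among low sites 23.2% gained, and this share was 23.1% at sites with 1 to 2 neighbours and 23.3% at sites with 3 or more. Among high sites 49.2% lost. On uncorrected counts 4087 sites gained and 7142 lost, and the share gained was 36.4% in place of 47.8%. The balance of gain and loss also turned with single samples and with the model: 5327 sites gained and 3136 lost without K562, 3547 and 2719 without adult donor 2, 4299 and 4215 without adult donor 3, 3880 and 3377 without adult donor 4, and 3283 and 2770 with limma on log2 odds, which called 6053 sites. At least 100 reads per sample left 4118 calls, 1735 gained and 2383 lost.

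Several sites went from nearly unmethylated in adult blood to nearly fully methylated in all 3 leukaemia samples. Position 75403878 of chromosome 17 was at 1.07% ± 0.873 in adult blood (SD, n = 4) and at 98.2% in AML (24 reads, 95% interval 89.8% to 100%), 100% in HEL (110 reads) and 99.7% in K562 (296 reads). Position 53524924 of chromosome 16 was at 1.66% ± 0.731 in adult blood and at 97.4% or above in each leukaemia sample. Position 16602756 of chromosome 10 was at 1.09% ± 0.41 in adult blood and at 96.6%, 100% and 99.6% in AML, HEL and K562. Adjusted p was 0.000123 at each of these sites in the quasi-binomial model with limma moderation. In the other direction, position 42264733 of chromosome 22 was at 98.1% ± 0.648 in adult blood and at 0% in AML (45 reads, interval to 16.7%), 6.3% in HEL (168 reads) and 0% in K562 (274 reads). Position 157144775 of chromosome 7 was at 94.4% ± 0.96 in adult blood and at 0%, 3% and 0.3% in AML, HEL and K562. Position 1994984 of chromosome 1 was at 90.3% ± 2.91 in adult blood and at 6.2%, 7.4% and 1% in the same samples.

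Windows of 100 kb were ranked by their number of gained and by their number of lost sites, without a test of clustering. Such a ranking favours windows with many sites. The window with the most gained sites was chromosome 10 from 8100001 to 8200000, where 17 of 22 sites gained and none lost, and the mean rose from 2.24% ± 0.0924 in adult blood to 52.2% in AML, 31.6% in HEL and 28.9% in K562. On chromosome 2 from 5700001 to 5800000, 15 of 15 sites gained, with means of 2.74% ± 0.703 in adult blood, 73.1% in AML, 58.8% in HEL and 37.2% in K562. On chromosome 12 from 129200001 to 129300000, 15 of 19 sites gained and 2 lost. The window with the most lost sites was chromosome 16 from 1000001 to 1100000, where 31 of 51 sites lost and none gained. The mean there was 71.3% ± 3.27 in adult blood, 67.6% in AML, 25.2% in HEL and 6.09% in K562. In the next window, from 1100001 to 1200000, 30 of 53 sites lost and 4 gained. On chromosome 1 from 2700001 to 2800000, 23 of 26 sites lost, and the means were 90.3% ± 3.14, 79.6%, 14.4% and 2.4% in the same order. Of 7246 windows with a measured site, 2013 held a gained site, 2356 a lost site and 515 both.

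Taken singly, the leukaemia libraries differed in the balance of gain and loss. AML gained 4295 and lost 1089 of 36612 sites, HEL gained 5731 and lost 4602 of 36718, and K562 gained 3922 and lost 8496 of 35891. By the same rule adult donors against each other gained between 6 and 35 sites and lost between 11 and 62 of 38613, and cord samples gained 233 and 206 and lost 70 and 61. At high sites 5.7% were lost in AML, 33.5% in HEL and 62.3% in K562. At low sites 16.1%, 21.5% and 16.4% were gained. On uncorrected counts AML gained 3189 and lost 2333 sites, HEL gained 4189 and lost 5567, and K562 gained 2891 and lost 9142. In HEL loss thus exceeded gain on uncorrected counts, and it did so on corrected values at 100 reads, with 2265 gained and 2620 lost.

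**Figure D2:**
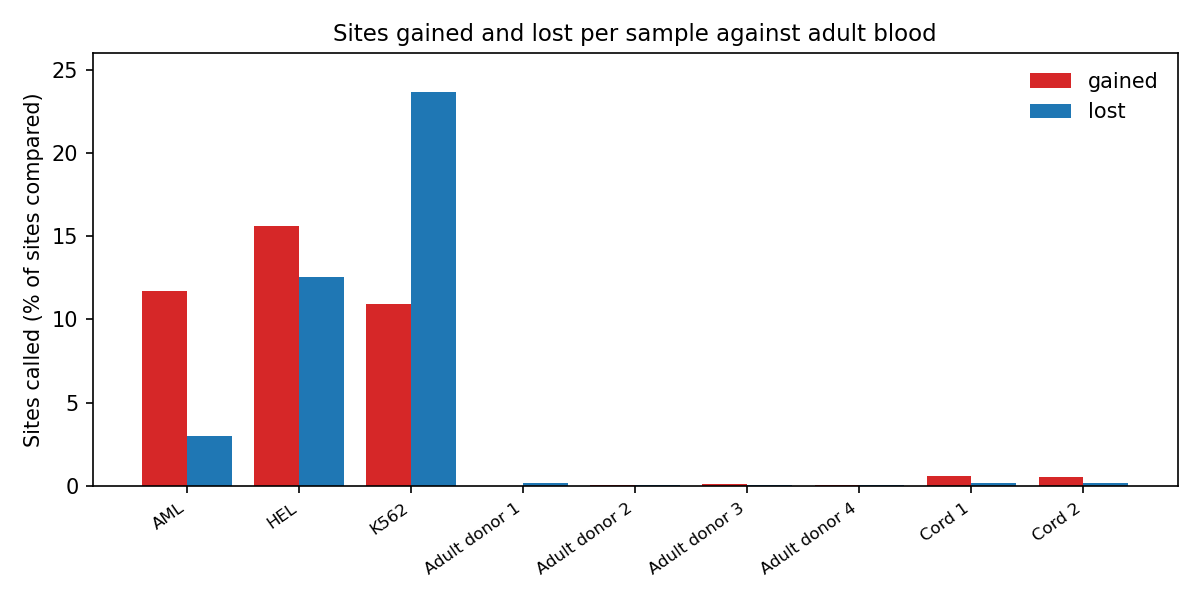
Percent of compared autosomal sites called gained (red bars) or lost (blue bars) in each leukaemia library and cord sample against the 4 adult donors, and in each adult donor against the other 3. Gained sites make up 11.7% in AML, 15.6% in HEL and 10.9% in K562, while adult donors and cord samples stay under 1%.

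The sites of greatest change in AML and HEL were often called in another library as well, and those of K562 mostly were not. Of the 10 named sites of each library, 7 of AML, 10 of HEL and 1 of K562 were called in the same direction in at least 1 of the other leukaemia libraries. Among all calls at sites covered in the 3 libraries, HEL and K562 shared 3955 lost sites (of 4209 and 7718). They also shared 2349 gained sites (of 5234 and 3695), so sharing was common beyond the named sites. Position 139577613 of chromosome 7, with no other listed site within 500 bp, was at 97.5% in AML (156 reads, 95% interval 95.2% to 98.8%), 0.826% ± 1.02 in adult blood, 0% in HEL and 34.5% in K562 (433 reads, interval 29.1% to 40.2%), so that K562 also gained. Position 10613665 of chromosome 1 was at 0% in AML (106 reads, interval to 7.69%), 97.2% ± 1.01 in adult blood, 99.3% in HEL and 90.9% in K562. In HEL, position 49003119 of chromosome 3 was at 100% (107 reads, interval from 98.7%), as against 0.217% ± 0.153 in adult blood, 0% in AML and 97.4% in K562. Position 168980878 of chromosome 6 was at 0% in HEL (228 reads, interval to 4.31%) and 0.7% in K562, with 98.6% ± 0.511 in adult blood and 88.5% in AML. In K562, position 71576221 of chromosome 10 was at 100% (191 reads, interval from 99.1%), with 0.279% ± 0.137 in adult blood, 0% in AML and 23.3% in HEL. Position 72928981 of chromosome 18 was at 0% in K562 (219 reads, interval to 3.64%) and at 99.9% ± 0.123 in adult blood, 100% in AML and 100% in HEL.

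The 3 libraries shared part of their calls. Of 33619 sites covered in all, 1164 were gained in AML, HEL and K562 and 549 were lost in the 3, as against 67.4 and 29.7 for lists independent over all sites. Low sites cannot be lost and high sites cannot be gained by 30 points, so lists independent within the low, intermediate and high classes are the closer reference, and these gave 137 and 187. Simulated unchanged libraries against the same adult donors had at most 9 calls in a direction and shared none, which bears on false calls alone. HEL and K562 shared 2349 gained sites, with 817 for independent lists within classes, and 3955 lost sites, with 2528. With different pairs of adult donors as controls for each line, the shared counts were 2330 and 2350 gained and 3902 and 3972 lost. AML and HEL shared 2366 gained sites, with 889 for independent lists within classes, and 303 sites were gained in a library and lost in another.

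**Figure D3:**
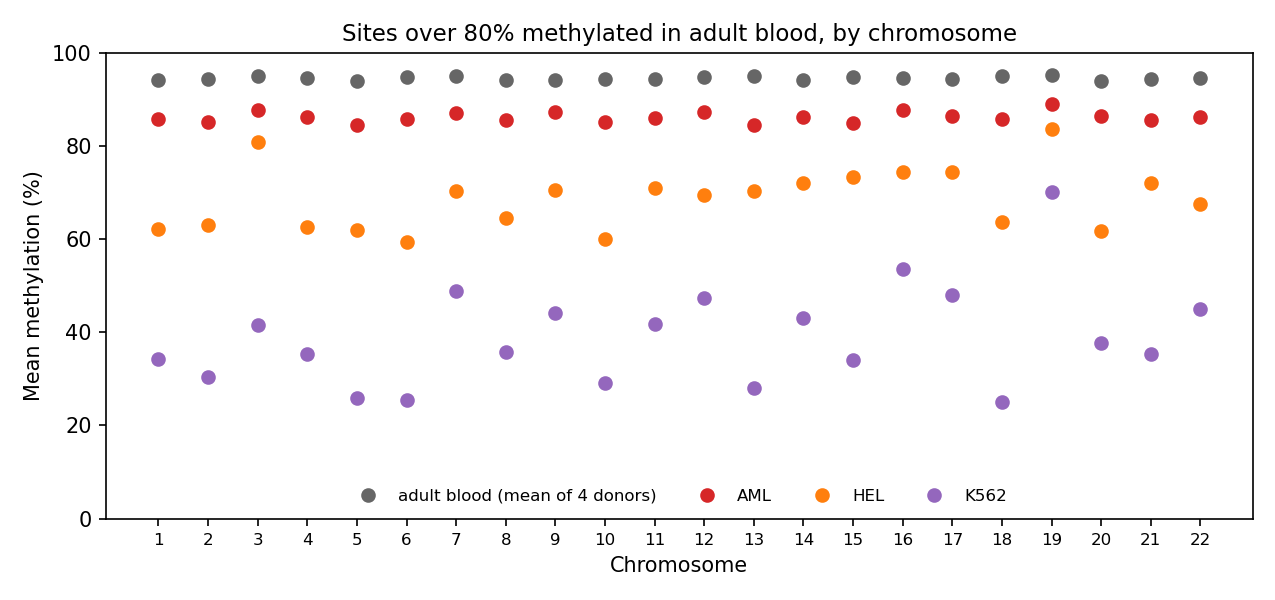
Mean methylation in percent of sites high in adult blood on each autosome, for the mean of the 4 adult donors, AML, HEL and K562 (points). K562 ranges from 25.1% on chromosome 18 to 70.2% on chromosome 19, while adult blood stays between 93.9% and 95.2%.

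Loss at high sites varied between chromosomes in the cell lines. This comparison was chosen after the values were seen and has no test. On chromosome 19 (970 high sites) the mean was 70.2% in K562 and 83.6% in HEL, and on chromosome 18 (210 sites) it was 25.1% and 63.8%. K562 was also low on chromosome 6 at 25.6% and chromosome 5 at 25.9%. In AML the chromosome means lay between 84.5% and 88.9%, and in adult blood between 93.9% and 95.2%. Among sites with 1 to 2 neighbours alone, the K562 means were 69.2% on chromosome 19 and 23.7% on chromosome 18.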

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

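The tests of the correction factors, and that of depth for adult donor 1, were chosen after their results were seen, as was the count of other splits for leukaemia. The depth test and the other splits for cord blood were set before.

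Mean methylation over all 33436 sites lay above the adult range (32.8% to 34.9%) in AML at 38.9% and in HEL at 36.8%, and below it in K562 at 24.1%. The difference between these libraries was not tested, and on uncorrected counts AML was at 32.5%, HEL at 30.4% and K562 at 19.2%, against an adult mean of 32.7%. On corrected values at 100 reads, AML was at 33.6%, HEL at 28.5% and K562 at 17.8%, against 30.3%, so HEL was then below adult blood.

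In data not used for methylation, the cell lines had runs of at least 4 consecutive sites without a read, among sites with at least 20 reads in every healthy sample. HEL had 6 such sites on chromosome 9 from 63533 to 429532, where 890 reads would follow from its depth, 6 from 962116 to 1041830 (1236 reads) and 7 from 21549368 to 23442248 (1023 reads). K562 had the same 7 sites on chromosome 9 without a read (1437 reads by its depth) and 4 on chromosome 10 from 126690496 to 126705761 (514 reads). A count of 0 allows up to 3 reads, and no healthy sample had under 603 reads in any of these runs.

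Adult donor 1 stood apart at high sites, with a mean of 92.2% where the other adult donors were at 95.1%, 95.4% and 95.6%; chance flags about 1 in 20 such groups. With 20 reads per site in every donor the gap was 2.80 points, where it was 2.90 at full depth. The ratio of gap to range (0.827) then fell just under its critical value. Drawing reads at random leaves the expected mean of a donor unchanged, so this cannot decide whether read depth plays a part. On uncorrected percentages the ratio was 0.52, so the correction factors may produce part of the gap. Donor 1 was still the lowest there, at 91.5%, with donors 2, 3 and 4 at 93.2%, 92.8% and 94.0%. A single wrong factor would shift the log odds of every class alike, whereas the shift of donor 1 was 0.131 at low, -0.347 at intermediate and -0.577 at high sites, but low sites hold few methylated reads and the step from intermediate to high sites (-0.23, with 0.161, -0.0385 and 0.0828 in the other donors) was under 2 times that of another donor, which leaves this open. No biological explanation was tested, since the labels separate no adult donor from the others.

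Most cord blood calls were higher in cord blood (73.3%). Unequal depth is argued against, because with 20 reads per site in every sample the share was 76.0% of 430 calls. The correction factors may account for it, since the share was 43.6% on uncorrected counts, and which scale is nearer the truth stays open, though the correction lowered the mean absolute difference between libraries of a donor from 2.30 to 1.74 points. The real grouping gave 1257 calls and the highest of the other 14 splits of the 6 samples gave 34. Only 1 of 15 splits reached the real count, too few splits for a share under 0.05. Every other split also put cord and adult samples into the same group. That widens the spread within the group, so few calls could be made there by construction, and the splits do not exclude chance. A biological difference between cord and adult blood stays open and untested.

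For leukaemia against adult blood, 1 of the 35 splits of the 7 samples, the real one, reached 10706 calls, and the highest of the others gave 0. Each of the others put leukaemia and adult samples into the same group. That widens the spread within the group, so few calls could be made there by construction. The splits therefore do not exclude chance.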

How the results depend on the processing

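Uncorrected counts, centred log odds, intermediate sites alone and every alternative for single-library means were chosen after seeing the data; the others were set before. Of the alternatives, 139 kept the direction and side of the threshold where a test was run, or a count within 1.5 times. A further 36 were weaker, 9 moved in value, 8 reversed direction and 3 were stronger. Causes were not tested except where the construction shows them. Cord blood calls (1257) became 3591 with no minimum difference, 574 at 20 points and 2 with limma on log2 odds (100% higher in cord blood). The share higher in cord blood was 43.6% on uncorrected counts and 53.8% with centred log odds, which draw it towards balance by construction. Leukaemia calls (10706) became 4118 at 100 reads, where fewer sites were tested, 6053 with limma, and between 6266 (without adult donor 2) and 14088 (without AML) with a sample left out. At 100 reads HEL gained 2265 and lost 2620 sites and K562 gained 1639 and lost 4316, again of fewer sites. AML lost 1786 sites at 20 points and 2333 on uncorrected counts. With medians over sites, the cord difference was -0.434 points and the leukaemia difference 8.00 over all sites (exact permutation p = 0.0286), 0.751 at low (p = 0.257) and -25.2 at high sites (p = 0.0571), so the call over all sites was made and those of both classes were lost. On uncorrected counts the cord difference was -0.244. With a sample left out, the leukaemia difference ranged from -4.05 to 3.98 (without K562) over all sites, from 12.03 to 14.8 at low sites and from -38.8 to -16.5 at high sites; these designs cannot reach p under 0.05. Against adult blood, AML differed by 3.31 points over all sites at 100 reads and -0.228 on uncorrected counts, HEL by -1.82 and -2.27, and K562 by -12.5 and -13.5. Within-donor and between-donor differences were 1.74 and 2.47 as mean absolute differences, 6.04 and 8.85 at intermediate sites, and 0.663 and 0.686 on uncorrected counts, where the call was lost. With a library left out they ranged from 0.6 to 0.7 and from 0.712 to 0.812, and the call was lost in 4 of 8 cases. Of the 13 libraries, AML had the fewest autosomal sites at 20 reads or more (38693) and HEL at 100 reads or more (25197). In the simulated cord comparison limma recovered 0% of changes of 20 and of 40 points.

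With the replicate number as a block, the quasi-binomial model called 0 cord blood sites, with 4678 at an unadjusted p under 0.05 and 1 residual degree of freedom. The numbers do not pair the samples as far as the labels say, and deviations of same-numbered samples did not correlate across sites (r = -0.00529 and -0.00011).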

Other observations

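The test of repeated counting for gain in HEL and K562 was chosen after its result was seen, and the correlations over separate sites after those over the same sites; the variance shares themselves had been seen before the other tests were set.

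At 233 sites every healthy sample lay between 35% and 65%. AML stayed in that range at 68 of them, HEL at 31 and K562 at 28. Every healthy sample was used to choose the sites, so these counts have no healthy baseline. They were not repeated on uncorrected counts. HEL was under 20% at 88 and over 80% at 70, K562 was under 20% at 142 and over 80% at 27, and AML was under 20% at 38 and over 80% at 72. There were 3 windows of 10 kb with at least 3 such sites. On chromosome 11 from 2677292 to 2678318, 7 sites averaged 45.6% ± 2.22 in adult blood (SD, n = 4), 47.2% in cord blood, 47.7% in AML, 0.586% in HEL (1420 reads) and 29.0% in K562. On chromosome 8 from 141178728 to 141178914, 3 sites averaged 51.0% ± 6.80 in adult blood, 55.8% in AML, 96.3% in HEL and 49.9% in K562. On chromosome 20 from 56863232 to 56864679, 4 sites averaged 52.2% ± 4.50 in adult blood, 75.8% in AML, 25.3% in HEL and 27.8% in K562. These regions were chosen after their values were seen.

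Loss at high sites was regional in the cell lines. Of 243 windows of 1 Mb with at least 10 high sites, HEL averaged under 20% in 11 and at least 80% in 109, K562 under 20% in 49 and at least 80% in 21, and AML at least 80% in 218, with 68.4% its lowest. On chromosome 10 from 132000001 to 133000000, 16 high sites averaged 92.5% in adult blood, 74.9% in AML, 4.21% in HEL and 0.8% in K562. On chromosome 19 from 10000001 to 11000000, 29 sites averaged 96.3% in adult blood, 92.1% in AML, 99.2% in HEL and 94.6% in K562. The window of chromosome 18 from 13000001 to 14000000 parted the lines, with 73.7% in HEL and 0.558% in K562.

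Windows of 1 Mb accounted for 0.382 of the variance in the difference from adult blood at high sites in HEL and 0.385 in K562, as against 0.0499 in AML, which lay within the adult donors' range (0.049 to 0.0949). These shares are relative to each sample's own spread. In points, the SD between windows was 2.87 in AML, 22.7 in HEL and 24.5 in K562, against 0.577 to 1.31 in the adult donors. Permuting sites within density classes 1000 times gave at most 0.0188 in either line, so these classes do not account for the share. Since 8822 of the 10135 high sites fell in 1 class, this says little about density on the scale of the windows. Repeated counts of neighbouring sites are argued against, since with 1 site per 10 kb the share was at least 0.301 in both lines. Read depth is argued against as well, since with 20 reads per site the share was at least 0.375. Window means of high sites, taken from alternate blocks of 100 kb so that no site was used in both libraries, correlated in HEL and K562 (Pearson r = 0.482 across 281 windows, permutation p = 0.001, the smallest possible; windows are not independent replicates), so that large domains of loss may be shared by the lines, a hypothesis found and tested on the same data, whereas AML correlated with HEL at 0.348 and with K562 at 0.302 but between its own blocks at 0.167 (HEL 0.672, K562 0.585; each p = 0.001), so whether AML has such domains stays open. At low sites the window share was 0.306 in AML and 0.199 with 1 site per 10 kb, while in HEL and K562 it fell from 0.151 and 0.158 to at most 0.0283, and between blocks of the same library window means correlated at 0.245 in AML (permutation p = 0.001), 0.0755 in HEL (permutation p = 0.011) and 0.0314 in K562 (permutation p = 0.246), so gain may extend beyond single blocks in AML and in HEL, and this was not detected in K562. Between libraries the same measure was 0.115 in AML and HEL (permutation p = 0.001), 0.0476 in AML and K562 (permutation p = 0.0839) and 0.0216 in HEL and K562 (permutation p = 0.464), where the low values within each line leave open whether regions of gain are shared; culture and the type of leukaemia cannot be separated in 3 single libraries and stay untested.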
